A study of Cucumis melo with 24 samples.

How the data were processed

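RNA from the fruit flesh of wild-type (WT) melon, Cucumis melo, and of the cmnac-nor mutant was sequenced at 15, 25, 35 and 45 days after pollination (DAP). Each genotype and age had 3 libraries, which makes 24 libraries in 8 groups. Per the labels' protocols, RNA was taken up in Trizol, cleaned on columns with DNase treatment and made into libraries with a TruSeq RNA kit, and the design text names an Illumina NovaSeq instrument. The submitters' processing notes name TopHat2, HISAT2, StringTie and Cufflinks without a version. The role of each tool, the genome build and the annotation are not given in the sources used here. Groups and replicate numbers were taken from the sample titles, which match the column names of the table.

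The deposited values were treated as TPM made by the authors, the abundance of a gene's transcripts relative to all transcripts of its library, although no header or label names the unit. That reading comes from the values, which have decimals and sum to between 927159 and 963192 per library over the 29980 genes listed, just under the total that TPM over all transcripts would have. TPM are set relative to the other transcripts of the same library, so a few very abundant transcripts in a library lower the values of all others. TPM also keep no read depth, so the depth of each library is unknown, no counting interval can be given, and count models were not used. Libraries held between 13820 and 16044 genes at 1 TPM or more, and 7471 genes were listed at 0 in every library.

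Genes were tested where at least 3 of the 24 libraries reached 1 TPM, which left 17658 genes. The test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(TPM + 1), with all 24 libraries in 1 model of 8 group means, empirical Bayes moderation with a mean-variance trend, and no covariate. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each comparison. Fold changes are therefore on the log2(TPM + 1) scale, which understates the change of low genes. The comparisons were mutant minus WT at each age, each step between neighbouring ages within a genotype, the difference of each step between genotypes, and an F test over all step differences. The main design, the alternatives, the gene lists and the rule for named genes were set before the data were examined.

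The named genes of each genotype comparison were the gene mutated in the line, the 5 largest changes in each direction, and up to 4 members of each list by smallest adjusted p. Genes of the largest changes had to be called, described in the table, without overlap between the libraries of both groups, and at a mean of 10 TPM or more in the higher group. List members had to be called with the same minimum mean. For steps and step differences the 3 largest in each direction were taken. For 15 DAP the genes described from this rule, other than CmNAC-NOR, are ones that kept their call in the fit to the groups of the comparison alone and without each library in turn, a choice made after the values were seen, and any gene named outside the rule is said to be chosen after its values were seen. Gene names are the descriptions in the deposited table. Of its identifiers, 0 matched the reference gene table of another melon assembly (USDA_Cmelo_AY_1.0), so no coordinates are given.

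The 32 gene lists, covering ripening pathways, regulators, hormones, stress and markers of other tissues, were made from words in those descriptions. Each was tested as a competitive set with camera (limma) at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. A camera result says whether members moved more to one side than the other genes tested. The number of members called is given over all genes tested and adjusted over the list alone.

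The tests were tried on simulated data made from the real genes, with 200 of 17658 genes changed. With equal spread in all groups, false calls made up between 4.63% and 5.96% of all calls in the comparisons simulated. With simulated log values below 0 set to 0, since real ones cannot lie lower, they made up 10.1%, 6.5%, 5.55% and 6.55% for the genotypes at the 4 ages and 6.82%, 5.16% and 5.57% for the step differences. The real groups do not vary alike. Relative to the spread pooled over groups, and over the 11143 genes with higher values, the SD was 1.07 in WT and 1.27 in the mutant at 15 DAP, 0.725 and 0.851 at 25 DAP, 1.15 and 1.16 at 35 DAP, and 0.75 and 0.879 at 45 DAP. Simulated with these spreads and the same floor at 0, the share of false calls was 31.1% for the genotype comparison at 15 DAP, 1.05% at 25 DAP, 21.8% at 35 DAP and 1.22% at 45 DAP. For the step differences it was 7.74%, 6.03% and 6.16% in order of age. A fit to the groups of the comparison alone gave 6.82%, 7.6%, 6.84% and 6.5% at the 4 ages. All these shares depend on how many genes change. The real comparisons called many more than 200 genes, so the shares are not rates for the real calls. The pooled fit recovered 64.3%, 60.7%, 61.5% and 56.7% of the 2-fold changes at the 4 ages and 87.3%, 81.2%, 83% and 78.7% of the 4-fold changes. The fit to the groups alone recovered 13.5%, 54.7%, 18.8% and 45.7% of the 2-fold changes and 66.2%, 81.2%, 65.2% and 76.7% of the 4-fold changes.

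Alternatives were a pseudocount of 0.1, no filter on low values, a filter at 5 TPM, median-of-ratios scaling, quantile normalization, array weights, robust moderation, a fit to the groups of the comparison alone, the replicate number as a block, an added 2-fold minimum, and leaving out each library in turn. Gene-by-gene array weights, removal of the 50 most abundant genes, list tests fitted to the groups of the comparison alone, and cleaned lists without members whose description shows another function were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.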

Results

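RNA was sequenced from the flesh of melon fruit of 2 genotypes, wild type (WT) and the cmnac-nor mutant, at 15, 25, 35 and 45 days after pollination (DAP), with 3 libraries in each of the 8 groups. CmNAC-NOR is a NAC-domain transcription factor gene, and its tomato relative is known as a regulator of ripening. The comparison at each age asks which genes differ between the genotypes at that age, a step asks which genes change between neighbouring ages within a genotype, and a step difference asks which of these changes differ between genotypes. Levels are mean TPM ± SD of 3 libraries, and changes are log2 differences of TPM + 1 with their standard error (SE), mutant minus WT unless a step is named. The depth of the libraries is unknown. Nothing in the labels says that the 3 libraries of a group came from separate fruits or plants, so p-values measure only the spread between these samples, which may be technical.

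WT libraries from 25 DAP on correlated less with the 15 DAP libraries of their genotype than mutant libraries did. The mean correlation with the 15 DAP libraries of the same genotype, across tested genes, was 0.796 at 25 DAP, 0.751 at 35 DAP and 0.731 at 45 DAP in WT. In the mutant the same values were 0.92, 0.909 and 0.858. Between genotypes the libraries correlated at 0.886 to 0.928 at 15 DAP, 0.743 to 0.788 at 25 DAP, 0.703 to 0.773 at 35 DAP and 0.76 to 0.785 at 45 DAP. Libraries of the same group correlated at 0.913 to 0.98. Genes are not independent replicates, and no p is attached to these correlations. The first 3 principal components held 57.6%, 8.22% and 7.65% of the variance.

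**Figure D1:**
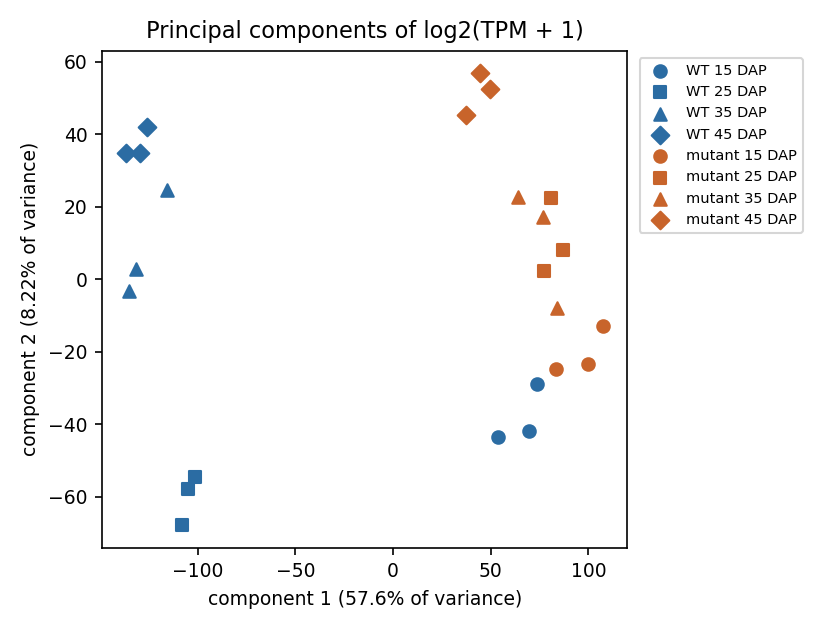
Principal components of log2(TPM + 1) over the tested genes, with 1 point per library; the axes give the share of variance, 57.6% and 8.22%, colour gives genotype and marker shape gives age in DAP. WT libraries from 25 DAP on lie apart from the WT libraries at 15 DAP and from the mutant libraries.

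CmNAC-NOR itself (MELO3C016540.2, identifier known from published work) was transcribed in both genotypes. In WT its level was 777 ± 230 TPM at 15 DAP, 1420 ± 39.8 at 25 DAP, 1050 ± 246 at 35 DAP and 458 ± 46.1 at 45 DAP. In the mutant it was 149 ± 153, 543 ± 86.8, 1150 ± 108 and 1860 ± 55.9 at the same ages. The gene was thus lower in the mutant at 15 DAP (log2 change -3.0, SE 0.52, limma adjusted p = 0.000558) and 25 DAP (-1.39, SE 0.52, adjusted p = 0.025). It did not pass the test at 35 DAP (0.16, SE 0.52, adjusted p = 0.81) and was higher at 45 DAP (2.03, SE 0.52, adjusted p = 0.00255). The 3 mutant libraries at 15 DAP read 24.61, 101.51 and 319.78 TPM. A mutation can alter a protein without lowering its transcript, so these levels are no check of the genotype labels. The call at 15 DAP ended in the fit to its own groups (adjusted p = 0.155; 1.75e-06 to 0.155 over the alternatives). The call at 25 DAP ended under quantile normalization (-1.14, adjusted p = 0.0894, with 2.84e-05 to 0.0894 over the alternatives) and without WT replicate 1 (0.051), 2 (0.05) or 3 (0.0561) or mutant replicate 1 (0.0597) or 2 (0.0658) at that age. It held in the fit to its own groups, where WT libraries read 1392.25 to 1462.76 TPM and mutant libraries 481.61 to 642.18. The SE of 0.52 is pooled over all 24 libraries, among them the scattered mutant libraries at 15 DAP.

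**Figure D2:**
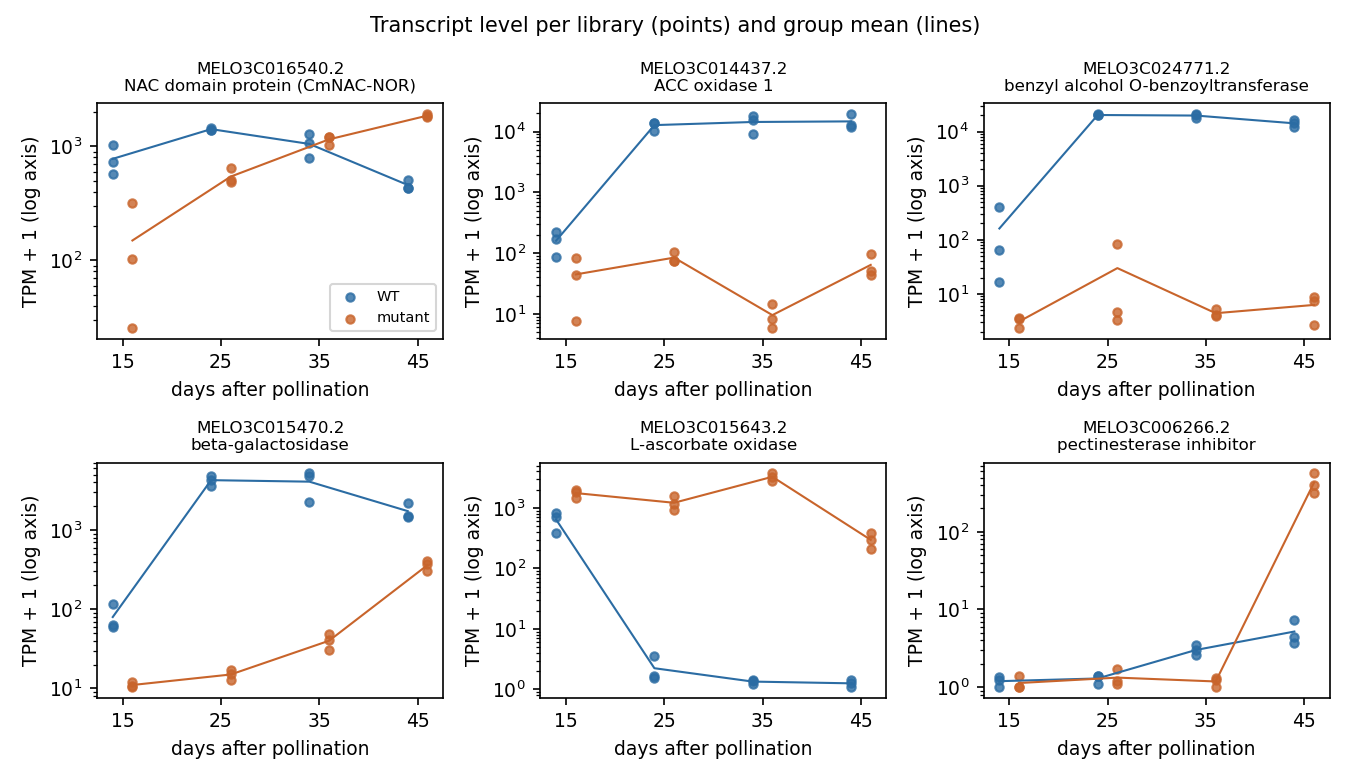
Levels of 6 genes in each library (points, offset by genotype) with group means (lines); the horizontal axis is age in DAP and the vertical axis is TPM + 1 on a log scale. The genes other than CmNAC-NOR were chosen for display after their values were seen; ACC oxidase 1 reached 14700 TPM in WT and 63.1 in the mutant at 45 DAP.

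At 15 DAP several transcripts of WT flesh were far lower in the mutant. Acyl carrier protein 1 (MELO3C024326.2), a carrier in fatty acid synthesis, stood at 476 ± 174 TPM in WT and 1.83 ± 1.25 in the mutant (log2 change -7.40, SE 0.81, adjusted p = 4.81e-06). A cytochrome P450 71A1-like gene (MELO3C025798.2) was at 184 ± 145 and 0.39 ± 0.178 TPM (-6.78), and an acidic endochitinase (MELO3C006965.2) at 154 ± 26.5 and 1.43 ± 0.852 TPM (-6.04). The branched-chain amino acid aminotransferase MELO3C010776.2, of an enzyme class that feeds aroma volatiles, was lower by a log2 change of -5.15 (SE 0.79), and the polygalacturonases MELO3C016494.2 and MELO3C027277.2, which degrade pectin, by -5.31 and -5.93. Higher in the mutant were a nucleoside diphosphate kinase (MELO3C016294.2, 11.2 ± 9.52 to 227 ± 66.7 TPM, log2 change 4.61), the cysteine proteinase inhibitor MELO3C027975.2 (4.60), the heat shock 21-like gene MELO3C018228.2 (4.32) and p24delta9 (MELO3C033124.2, 0.02 ± 0.0346 to 13.9 ± 1.11 TPM, 3.87).

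Of the photosynthesis list at 15 DAP, 30 of 83 members rose and 2 fell in the mutant (34 and 2 adjusted over the list alone), among them the chlorophyll a-b binding protein MELO3C007154.2 (5.01 ± 1.05 to 34.4 ± 8.99 TPM, log2 change 2.54, SE 0.41). Camera called the list higher (adjusted p = 0.000109), but not with an estimated correlation (adjusted p = 0.752). Of the abscisic acid list, 1 of 23 rose and 7 fell (1 and 8 adjusted over the list alone, camera adjusted p = 0.00738). This was the 1 call of the age that held with an estimated correlation (adjusted p = 0.0435). The estimate for this list was -0.00193, below the preset of 0.01, against 0.0359 to 0.25 for the other lists called. That setting thus raised the correlation for the others and not for this list. The call of this list ended without mutant replicate 1 (adjusted p = 0.171, with 0.000542 to 0.171 over the alternatives). The carotenoid cleavage list, which shares 3 genes with it, had 4 of 7 members lower, also adjusted over the list alone (camera adjusted p = 0.00861; adjusted p = 0.149 with an estimated correlation). That call ended without mutant replicate 1 (adjusted p = 0.0756; 0.00436 to 0.149 over the alternatives). The 9-cis-epoxycarotenoid dioxygenase MELO3C007127.2, of an enzyme class that acts early in abscisic acid synthesis, was at 48.8 ± 47.1 TPM in WT and 1.48 ± 1.18 in the mutant (log2 change -4.03). Beta-carotene hydroxylase MELO3C006938.2 (234 ± 15.8 against 55.3 ± 7.91 TPM, -2.07) and STAY-GREEN MELO3C005616.2 (99.7 ± 11.4 against 29.7 ± 3.54 TPM, -1.71), a gene of chlorophyll breakdown, were lower.

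Regulators at 15 DAP included NAC factors, of which 3 of 53 rose and 10 fell (4 and 12 adjusted over the list alone; camera adjusted p = 0.00803; adjusted p = 0.276 with an estimated correlation). NAC83 (MELO3C022342.2, log2 change -1.33), NAC100-like (MELO3C001996.2, -1.67) and NAC72-like (MELO3C018242.2, -2.35) were lower. Among MADS-box factors 1 of 36 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.0441; adjusted p = 0.586 with an estimated correlation). The AGAMOUS-type gene MELO3C019694.2 was at 630 ± 45.5 TPM in WT and 329 ± 42.1 in the mutant (-0.94, SE 0.11). Of the sucrose and galactosyl-sugar list 2 of 47 rose and 10 fell, also adjusted over the list alone (camera adjusted p = 0.0441; adjusted p = 0.752 with an estimated correlation), with a 6-phosphofructokinase (MELO3C015428.2), an enzyme of glycolysis, at 166 ± 81.2 and 25.9 ± 12.1 TPM (-2.63). The MADS-box call ended under quantile normalization (adjusted p = 0.0684), median-of-ratios scaling (0.0701), without WT replicate 1 (0.0852) and without mutant replicate 1 (0.187), in a range of 0.0191 to 0.586 over the alternatives. The sugar call ended under median-of-ratios scaling (adjusted p = 0.0505), quantile normalization (0.0522), with the cleaned list (0.118), without WT replicate 2 (0.114) and without mutant replicate 3 (0.158), in a range of 0.0251 to 0.752. The other 26 lists were not called (adjusted p 0.149 to 0.98).

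Among lists of other tissues at 15 DAP, the medians were -0.38 for phloem, -0.04 for seed, 0.01 for rind and 0.14 for organelle and ribosomal RNA (camera adjusted p = 0.149, 0.635, 0.423 and 0.211). Of 29 phloem genes 2 rose and 3 fell, also adjusted over the list alone. The phloem list was called lower in the fit to the groups of the comparison alone (adjusted p = 0.0171), without WT replicate 2 (0.0396) and without mutant replicate 2 (0.0456), in a range of 0.0171 to 0.752 over the alternatives. Of 60 senescence and proteolysis genes 5 rose and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.222). That list was called lower when cleaned (1 of 33 higher and 8 lower, adjusted p = 0.0135) and without mutant replicate 2 (0.0456), in a range of 0.0135 to 0.79. Of 14 ethylene perception and signalling genes 1 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.173). These were called lower without mutant replicate 3 (adjusted p = 0.0135; 0.0135 to 0.782 over the alternatives). Of 31 carotenoid synthesis genes 1 rose and 6 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.152). Their call, lower, came without WT replicate 3 (adjusted p = 0.0476) or mutant replicate 3 (0.0433; 0.0433 to 0.752 over the alternatives).

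The test at 15 DAP called 3232 genes, 1822 higher and 1410 lower in the mutant, 1254 of them by at least 2-fold. Fitted to the 6 libraries of the comparison alone it called 695 genes, 293 higher and 402 lower, and 69 of the 124 named genes lost their call. In simulated data that fit recovered 13.5% of 2-fold changes at this age, against 64.3% in the fit to all libraries, with 6.82% against 31.1% of calls false. Leaving out a library ended the call of 19 of the 124. The genes described here for this age, other than CmNAC-NOR, were picked from the 124 after the alternatives were seen, as ones that kept their call in that fit and without each library in turn. Without mutant replicate 2 the count was 2089. More genes were lower than higher without WT replicate 1 (1097 higher, 1302 lower), without mutant replicate 1 (1599 and 1957) and in the fit to the comparison alone, so the direction with more genes is not settled at this age.

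At 25 DAP benzyl alcohol O-benzoyltransferase (MELO3C024771.2), of a family that makes volatile esters, was at 20200 ± 418 TPM in WT and 28.9 ± 44.9 in the mutant (log2 change -10.87, SE 0.97, adjusted p = 1.38e-08). 1-aminocyclopropane-1-carboxylate (ACC) oxidase 1 (MELO3C014437.2), which catalyses the last step of ethylene synthesis, was at 12800 ± 2070 and 83.4 ± 15.9 TPM (-7.24, SE 0.60). A beta-galactosidase (MELO3C015470.2) and an endoglucanase-like gene (MELO3C005716.2, 704 ± 118 against 0.207 ± 0.324 TPM), both wall enzymes, were lower by log2 changes of -8.15 and -9.21. In the other direction, L-ascorbate oxidase (MELO3C015643.2) was at 1.24 ± 1.11 TPM in WT and 1210 ± 335 in the mutant (9.15, SE 0.31), and an auxin-responsive protein (MELO3C006476.2) at 0.367 ± 0.451 and 327 ± 27.1 TPM (7.96).

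Photosynthesis genes were lower in the mutant at 25 DAP, the reverse of their direction at 15 DAP. Of 83 members 3 rose and 58 fell, also adjusted over the list alone (camera adjusted p = 2.76e-18; adjusted p = 0.278 with an estimated correlation). The chlorophyll a-b binding protein MELO3C002727.2 was at 2120 ± 598 TPM in WT and 17.1 ± 3.88 in the mutant (log2 change -6.85), and photosystem I subunit N (MELO3C008060.2) was lower (-5.05). Of the carotenoid synthesis list 7 of 31 rose and 15 fell, also adjusted over the list alone (camera adjusted p = 0.000826; adjusted p = 0.635 with an estimated correlation), with 15-cis-zeta-carotene isomerase (MELO3C017709.2) at -3.63 and geranylgeranyl pyrophosphate synthase (MELO3C013320.2) at -1.99. Carotenoid cleavage had 3 of 7 members lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.0105; adjusted p = 0.278 with an estimated correlation). Its 9-cis-epoxycarotenoid dioxygenase MELO3C016224.2 was at 577 ± 19.7 TPM in WT and 26.8 ± 2.69 in the mutant (-4.38, SE 0.18). STAY-GREEN (MELO3C005616.2) was at 703 ± 116 and 24.4 ± 3.04 TPM (-4.79), while the chlorophyll breakdown list had 1 of 11 higher and 4 lower (camera adjusted p = 0.0565; the same counts adjusted over the list alone; median -0.03, mean -0.54). That list was called lower without WT replicate 2 (adjusted p = 0.0463) or 3 (0.049) and among cleaned lists (0.047), in a range of 0.0463 to 0.732 over the alternatives. Cleaning removed none of its own 11 members, so only the adjustment over the other lists differed there.

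At 25 DAP aroma and ethylene genes changed in both directions, and camera called none of these lists. Of 43 aroma genes 20 rose and 11 fell, also adjusted over the list alone (camera adjusted p = 0.555, direction lower; mean -0.04). Their median was 0.30, or 0.01 after median-of-ratios scaling and -0.13 after quantile normalization. The members that fell included the second O-benzoyltransferase (MELO3C024766.2, log2 change -10.53), the aminotransferase MELO3C010776.2 (9470 ± 1130 against 13.2 ± 17.1 TPM, -10.10) and a cinnamyl alcohol dehydrogenase (MELO3C018492.2, -6.24), and an alcohol dehydrogenase-like gene (MELO3C023685.2) rose by 6.30. Of 25 ethylene synthesis genes 13 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.961, median 0.72, or 0.40 and -0.01 in these scalings), with ACC oxidase 2 genes MELO3C027119.2 (3.14) and MELO3C027120.2 (2.50) higher. In the cleaned ethylene synthesis list 10 of 20 rose and 6 fell (median 0.53). Of 14 ethylene perception and signalling genes 8 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.961; median 0.53, or 0.20 and 0.29). Pectin genes had 48 of 78 higher and 13 lower (48 and 14 adjusted over the list alone; camera adjusted p = 0.788; median 1.04, or 0.86 and 0.44), and wall loosening genes 47 of 78 higher and 19 lower, also adjusted over the list alone (camera adjusted p = 0.961, direction lower; median 1.04, or 0.89 and 0.37, mean 0.55). Heat shock and chaperone genes had 41 of 127 higher and 38 lower, also adjusted over the list alone, and camera called them lower than other genes (adjusted p = 0.0471; adjusted p = 0.941 with an estimated correlation) although their median (0.09) and mean (0.04) were above 0; their median was -0.22 after median-of-ratios scaling and -0.27 after quantile normalization. That call ended under quantile normalization (adjusted p = 0.188), without WT replicate 1 (0.0571) and without mutant replicate 1 (0.0614), in a range of 0.0302 to 0.941 over the alternatives.

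The test at 25 DAP called 11815 genes, 8588 higher and 3227 lower in the mutant, and 6796 changed at least 2-fold. The median gene was higher in the mutant by 0.44, by 0.18 after median-of-ratios scaling and by -0.01 after quantile normalization. With these scalings 6770 genes were higher and 4842 lower, or 5322 higher and 5639 lower, so which direction held more genes depended on the scale. Relative to the median gene the photosynthesis list stood at -2.26, carotenoid cleavage at -1.61, carotenoid synthesis at -0.81 and heat shock at -0.35. Lists of other tissues gave medians of 1.95 for phloem, 0.88 for seed, 0.16 for rind and 0.30 for organelle and ribosomal RNA, with camera adjusted p of 0.119, 0.961, 0.328 and 0.496. After median-of-ratios scaling the medians were 1.69, 0.77, -0.02 and 0.05 and after quantile normalization 1.71, 0.39, -0.33 and -0.04, so those of rind and of organelle and ribosomal RNA changed sign. Of the 29 phloem genes 21 rose and 1 fell, and of 114 auxin genes 67 rose and 13 fell (camera adjusted p = 0.123), with the same counts adjusted over the list alone. Both lists were called higher under median-of-ratios scaling (adjusted p = 0.0302 each) and quantile normalization (0.00912 each), in a range of 0.00912 to 0.941 over the alternatives, the highest with an estimated correlation. Of 84 AP2/ERF factors 52 rose and 7 fell, also adjusted over the list alone (camera adjusted p = 0.231). They were called higher under median-of-ratios scaling (adjusted p = 0.0302) and quantile normalization (0.0186; 0.0186 to 0.941 over the alternatives). Of 62 organic acid genes 23 rose and 15 fell (23 and 14 adjusted over the list alone; camera adjusted p = 0.125, direction lower; median 0.08, or -0.21 with either scaling, mean -0.07). Their call, lower, came under median-of-ratios scaling (adjusted p = 0.0302; 0.0302 to 0.941 over the alternatives). Of 60 senescence and proteolysis genes 26 rose and 17 fell, also adjusted over the list alone (camera adjusted p = 0.274, direction lower; median 0.28, or 0.07 and 0 in these scalings, mean 0.74). The cleaned list, with 8 of 33 higher and 15 lower, was called lower (adjusted p = 0.00151). Over the alternatives to the full list, the cleaned list among them, the range was 0.00151 to 0.941.

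At 35 DAP O-benzoyltransferase MELO3C024771.2 was at 19800 ± 1830 TPM in WT and 3.39 ± 0.722 in the mutant (log2 change -12.15, SE 0.97, adjusted p = 2.84e-09), and ACC oxidase 1 (MELO3C014437.2) at 14400 ± 4600 and 8.57 ± 4.48 TPM (-10.60, SE 0.60). An ACC synthase (MELO3C021182.2), which makes the ethylene precursor, was at 196 ± 170 TPM in WT (-7.17). Metallothionein-like 4A (MELO3C003132.2) was at 24300 ± 1690 TPM in WT at 15 DAP and 27.2 ± 12.2 at 35 DAP, and at 13900 ± 1550 and 10900 ± 1490 TPM in the mutant (log2 change at 35 DAP 8.70, SE 0.50). L-ascorbate oxidase (MELO3C015643.2) stood at 0.347 ± 0.0874 and 3270 ± 463 TPM (11.24, SE 0.31).

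Auxin genes were higher in the mutant at 35 DAP, 72 of 114 against 15 lower (73 and 16 adjusted over the list alone; camera adjusted p = 0.0134; adjusted p = 1 with an estimated correlation). Auxin response factor MELO3C025758.2 was at 5.39 ± 0.423 TPM in WT and 210 ± 14.6 in the mutant (log2 change 5.05, SE 0.14), and the auxin-conjugating enzyme GH3.3 (MELO3C008672.2) was higher by 5.88. Phloem genes followed the same direction, 22 of 29 higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.0141; adjusted p = 1 with an estimated correlation), among them phloem protein 2-like A1 genes MELO3C027112.2 (2.37 ± 1.66 against 431 ± 37.8 TPM, 7.16) and MELO3C018681.2 (5.44). Their call ended in the fit to the groups of the comparison alone (adjusted p = 0.0799; 0.00276 to 1 over the alternatives). Photosynthesis genes had 6 of 83 higher and 38 lower, also adjusted over the list alone (camera adjusted p = 0.000129; adjusted p = 1 with an estimated correlation). Carotenoid cleavage had 5 of 7 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.0134; adjusted p = 0.283 with an estimated correlation). Phytoene synthase MELO3C014677.2, at the entry to carotenoid synthesis, was at 62.9 ± 33.2 TPM in WT and lower in the mutant (-5.64, SE 0.33). The carotenoid synthesis list was not called, with 12 of 31 higher and 13 lower, also adjusted over the list alone (camera adjusted p = 0.214).

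Heat shock and chaperone genes at 35 DAP had 40 of 127 higher and 58 lower (40 and 59 adjusted over the list alone; camera adjusted p = 0.0134; adjusted p = 1 with an estimated correlation), and the call ended under quantile normalization (adjusted p = 0.097; 0.00923 to 1 over the alternatives). The class I heat shock gene MELO3C020588.2 was at 86.4 ± 11.9 TPM in WT and 1.52 ± 0.58 in the mutant (log2 change -5.14). ACC oxidase homolog 6 (MELO3C022978.2) went the other way, 13.2 ± 13.4 against 1400 ± 90.7 TPM (7.04), as did the AGAMOUS gene MELO3C007181.2, 5.26 ± 0.393 against 159 ± 24.4 TPM (4.67). Of 25 ethylene synthesis genes 11 rose and 6 fell (12 and 6 adjusted over the list alone, camera adjusted p = 1, direction lower, median 0.62, mean -0.25). In the cleaned list 7 of 20 rose and 6 fell (median 0.26). Of 43 aroma genes 20 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 0.833, direction lower; median 0.37, mean -0.36), with pyruvate decarboxylase MELO3C009145.2 lower (-6.37). Pectin genes had 45 of 78 higher and 19 lower (46 and 19 adjusted over the list alone; camera adjusted p = 0.899) and wall loosening genes 37 of 78 higher and 17 lower (38 and 17 adjusted over the list alone; camera adjusted p = 0.867), with pectinesterases MELO3C002316.2 (-5.68) and MELO3C031619.2 (-5.10) among those lower.

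The test at 35 DAP called 11370 genes, 7270 higher and 4100 lower, 6429 of them by at least 2-fold. The median gene was at 0.27, at 0.15 after median-of-ratios scaling and at -0.03 after quantile normalization, and the calls then split into 6569 higher and 5026 lower, or 5338 and 6003. Relative to the median gene the auxin list stood at 0.95, phloem at 1.48, photosynthesis at -0.96, heat shock at -0.72 and carotenoid cleavage at -3.10. Medians of other tissue lists were 0.02 for seed, 0.10 for rind and 0.05 for organelle and ribosomal RNA (camera adjusted p = 0.514, 0.867 and 0.68, direction lower). They were -0.03, 0.03 and -0.06 after median-of-ratios scaling and -0.17, -0.59 and -0.29 after quantile normalization, so each changed sign in at least 1 scaling.

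At 45 DAP the cysteine proteinase inhibitor MELO3C018579.2 was at 2.8 ± 1.74 TPM in WT and 4510 ± 1110 in the mutant (log2 change 10.31, SE 0.51, adjusted p = 5.79e-12), and MELO3C008183.2 and MELO3C034352.2 of the same description were higher by 10.51 and 9.94. Another, MELO3C033110.2, was listed at 0 in the 3 WT libraries and at 1570 ± 758 TPM in the mutant. Sucrose synthase MELO3C025101.2 was at 5.36 ± 6.63 and 652 ± 160 TPM (7.2), polygalacturonase MELO3C011986.2 was higher by 6.31 and endoglucanase 5 (MELO3C023598.2) by 6.53. O-benzoyltransferase MELO3C024771.2 remained at 14200 ± 2230 TPM in WT and 5.25 ± 3.2 in the mutant (-11.31, SE 0.97), and ACC oxidase 1 (MELO3C014437.2) at 14700 ± 4070 and 63.1 ± 29.7 TPM (-7.90).

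Auxin and phloem genes were again higher in the mutant at 45 DAP. Of 114 auxin genes 73 rose and 16 fell, also adjusted over the list alone (camera adjusted p = 0.00117; adjusted p = 0.847 with an estimated correlation), with auxin-responsive protein MELO3C006476.2 at 0.217 ± 0.16 and 391 ± 118 TPM (log2 change 8.29). Of 29 phloem genes 16 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.000546; adjusted p = 0.847 with an estimated correlation), with MELO3C018681.2 at 0.0267 ± 0.0462 and 978 ± 81.9 TPM (9.90, SE 0.38) and a phloem lectin (MELO3C021760.2) higher by 9.06. Photosynthesis genes had 6 of 83 higher and 35 lower (6 and 31 adjusted over the list alone; camera adjusted p = 0.000416; adjusted p = 0.941 with an estimated correlation), although the PsbP family gene MELO3C004308.2 rose by 1.73. Heat shock and chaperone genes had 30 of 127 higher and 61 lower (30 and 65 adjusted over the list alone; camera adjusted p = 0.000416; adjusted p = 0.847 with an estimated correlation), among them MELO3C020588.2 (105 ± 4.56 against 4.63 ± 1.11 TPM, -4.25). Carotenoid cleavage had 4 of 7 lower and 0 higher, also adjusted over the list alone (camera adjusted p = 0.00965; adjusted p = 0.358 with an estimated correlation).

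Transcription factors with large changes at 45 DAP were a NAC gene (MELO3C012873.2, 333 ± 49 TPM in the mutant, log2 change 8.21), NAC83 (MELO3C022342.2, 10.5 ± 1.44 against 108 ± 17.4 TPM, 3.24) and MADS8-like (MELO3C022315.2, 5.12). NAC83 had been lower in the mutant at 15 DAP. Of 31 carotenoid synthesis genes 12 rose and 8 fell (13 and 8 adjusted over the list alone; camera adjusted p = 0.743, direction lower; median 0.21, or -0.18 after quantile normalization, mean 0.17). Beta-carotene hydroxylase MELO3C005704.2 was higher by 6.07 and phytoene synthase MELO3C014677.2 lower (-3.70). Pectin genes had 37 of 78 higher and 15 lower (38 and 16 adjusted over the list alone, camera adjusted p = 0.536), wall loosening genes 34 of 78 and 12, also adjusted over the list alone (camera adjusted p = 0.536), and ethylene synthesis genes 13 of 25 and 4, also adjusted over the list alone (camera adjusted p = 0.578). The cleaned ethylene synthesis list had 10 of 20 higher and 4 lower. Of 43 aroma genes 14 rose and 16 fell (15 and 17 adjusted over the list alone; camera adjusted p = 0.24), with 13-lipoxygenase MELO3C014637.2 lower (-5.29).

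The test at 45 DAP called 10677 genes, 6793 higher and 3884 lower, 5764 of them by at least 2-fold. The median gene was at 0.22, at 0.11 after median-of-ratios scaling and at -0.08 after quantile normalization, with calls of 6171 higher and 4757 lower, or 4749 and 5958. Relative to the median gene the auxin list stood at 1.08, phloem at 1.35, photosynthesis at -0.80, heat shock at -0.64 and carotenoid cleavage at -1.14. Medians of other tissue lists were 0.09 for seed, 0.56 for rind and 0.05 for organelle and ribosomal RNA (camera adjusted p = 0.535, 0.536 and 0.536). They were 0.07, 0.50 and -0.03 after median-of-ratios scaling and -0.22, 0.03 and -0.26 after quantile normalization, so those of seed and of organelle and ribosomal RNA changed sign. Of 84 AP2/ERF factors 43 rose and 11 fell (44 and 11 adjusted over the list alone; camera adjusted p = 0.268). These factors were called higher under quantile normalization (adjusted p = 0.0496; 0.0496 to 0.941 over the alternatives).

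**Figure D3:**
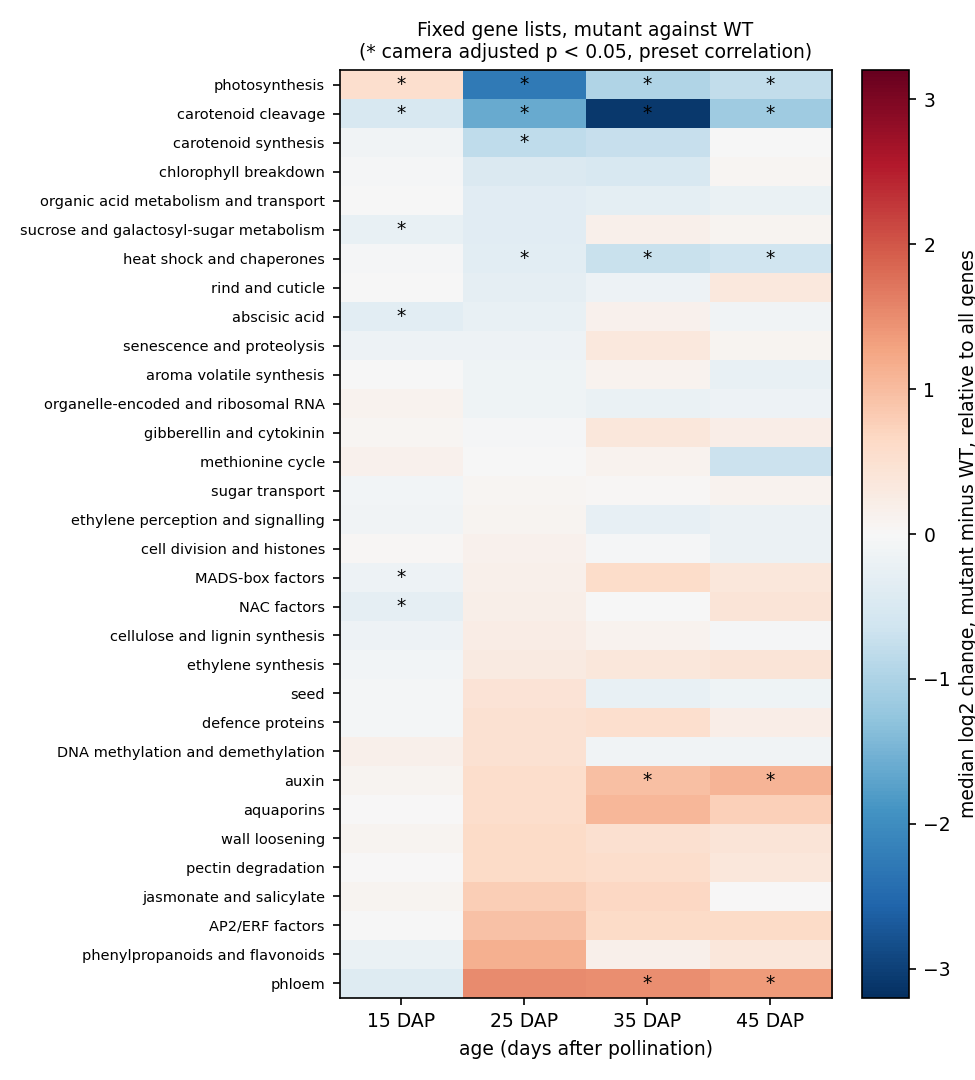
Median log2 change of each gene list relative to the median of all tested genes (colour) at each age, mutant minus WT (columns); an asterisk marks a camera adjusted p under 0.05 at the preset correlation. Photosynthesis stands at 0.53 at 15 DAP and -2.26 at 25 DAP, and phloem at 1.48 at 35 DAP and 1.35 at 45 DAP.

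Across ages, 4412 genes were higher in the mutant at 25, 35 and 45 DAP and 1676 were lower at all of these. Independent lists of these sizes would share 1360 and 165. The comparisons use different libraries at each age, but the fit gives each gene 1 spread for all ages. A gene of low spread is more easily called at every age. The values for independent lists are therefore no null for the overlap, and no test is attached to the excess. At all 4 ages 916 genes were higher and 454 lower, against 140 and 13 for independent lists. Without WT replicate 1 at 15 DAP 590 were higher at all 4 ages, and in fits to the groups of each comparison alone 176 were higher and 142 lower. Under quantile normalization 2617 genes were higher and 3240 lower at the 3 later ages, and median-of-ratios scaling gave 2515 lower. Opposite calls at 15 and 45 DAP were made for 655 genes, and at 25 and 45 DAP for 936.

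Within WT the largest rise and fall among the named genes of the 3 steps came from 15 to 25 DAP. An abscisic stress ripening-like gene (MELO3C025025.2) rose from 45.7 ± 67.3 to 10800 ± 1330 TPM (log2 change 9.13, SE 1.27), a polygalacturonase-like gene (MELO3C015128.2) from 10.1 ± 12.2 to 2720 ± 520 TPM (8.53) and O-benzoyltransferase MELO3C024771.2 by 8.05. L-ascorbate oxidase MELO3C015643.2 (-8.20), auxin-responsive protein MELO3C006476.2 (-8.07) and gibberellin-regulated protein 2 (MELO3C011008.2, -7.93) fell. From 25 to 35 DAP the cyclin-dependent kinase inhibitor SMR4 (MELO3C023871.2) rose from 7.84 ± 6.89 to 1780 ± 550 TPM (8.31) and a Kunitz trypsin inhibitor (MELO3C002175.2) by 5.55, while metallothionein-like 4A (MELO3C003132.2, -7.38) and ACC oxidase homolog 6 (MELO3C022978.2, -5.63) fell. From 35 to 45 DAP the 14 kDa proline-rich protein dc2.15 (MELO3C005540.2, 4.29) and a glycosyltransferase (MELO3C017673.2, 4.01) rose and the cysteine proteinase inhibitors MELO3C034352.2 (-5.18) and MELO3C034353.2 (-4.48) fell.

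The WT steps called 11190 genes (3275 higher, 7915 lower), 6873 (4385 and 2488) and 2821 (1272 and 1549) in order of age. Median-of-ratios scaling split the first step into 4652 and 6628 and quantile normalization into 5596 and 5101, with the median gene at -0.36, -0.16 and 0.02 in the 3 scalings; the second step split into 3230 and 3589 or 3300 and 2938. The count of the last step was 1011 in the fit to its own groups, 1533 without replicate 3 and 1678 without replicate 1 of the WT at 35 DAP, and without replicate 2 of that group 1991 genes were higher and 1644 lower.

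Within the mutant, heat shock genes were among the named genes that changed early, and wall and lipid transfer genes among those that rose late. The lists were not tested for steps within a genotype, so this describes single genes and not their groups. Class I heat shock genes MELO3C001614.2 (9.44 ± 16.4 to 1190 ± 264 TPM, log2 change 8.57) and MELO3C027124.2 (6.25) rose from 15 to 25 DAP. Among the 6 named genes of this step, 1 lost its call in the fit to its own groups and 1 on leaving out a library. From 25 to 35 DAP MELO3C027124.2 fell by 5.65 and MELO3C034100.2 fell by 8.50, while a SWEET sugar transporter (MELO3C026184.2, 5.09), a CBL-interacting kinase (MELO3C035201.2, 4.96) and an extensin-like gene (MELO3C017856.2, 4.65) rose. From 35 to 45 DAP a pectinesterase inhibitor (MELO3C006266.2) rose from 0.183 ± 0.168 to 429 ± 125 TPM (8.48, SE 0.26), a non-specific lipid transfer protein (MELO3C018657.2) from 14.2 ± 4.9 to 5180 ± 1550 TPM (8.42) and mannan endo-1,4-beta-mannosidase 1-like (MELO3C022162.2), a wall enzyme, by 8.21. A peroxidase (MELO3C014658.2, -7.06), a leucine-rich repeat gene (MELO3C032314.2, -6.23) and a cytochrome P450 (MELO3C022045.2, -5.22) fell.

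The mutant steps called 3366 genes (1932 higher, 1434 lower), 3622 (1901 and 1721) and 5164 (2306 and 2858) in order of age. Median-of-ratios scaling split the first into 1692 and 2054 and quantile normalization into 1872 and 2056. The first count was 705 in the fit to its own groups, 1940 without replicate 2 of the mutant at 25 DAP and 2051 without replicate 2 of the mutant at 15 DAP, and without replicate 3 of the mutant at 15 DAP 1581 genes were higher and 1706 lower.

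The step differences ask where the genotypes changed by different amounts. From 15 to 25 DAP the change of photosynthesis genes differed between genotypes, with 2 of 83 members changing upward in the mutant relative to WT and 57 downward (3 and 58 adjusted over the list alone; camera adjusted p = 1.66e-26; adjusted p = 0.179 with an estimated correlation). The chlorophyll a-b binding gene MELO3C002727.2 went from 12.7 ± 4.42 to 2120 ± 598 TPM in WT and from 51.6 ± 10.6 to 17.1 ± 3.88 in the mutant (difference of log2 changes -8.83, SE 0.60). Gibberellin-regulated protein 2 (MELO3C011008.2) went from 1700 ± 432 to 6.07 ± 2.45 TPM in WT and from 584 ± 411 to 3150 ± 1160 in the mutant (10.58, SE 1.03). Carotenoid synthesis genes had 4 of 31 upward and 10 downward, also adjusted over the list alone (camera adjusted p = 0.00794; adjusted p = 0.823 with an estimated correlation), and phloem genes 20 of 29 upward and 0 downward (21 and 0 adjusted over the list alone; camera adjusted p = 0.0163; adjusted p = 0.855 with an estimated correlation). The phloem call ended without replicate 1 of the WT (adjusted p = 0.0603) or of the mutant (0.0666) at 15 DAP, in a range of 0.000222 to 0.855.

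Some lists were called from 15 to 25 DAP only in alternatives. Of 84 AP2/ERF factors 39 went upward and 8 downward, also adjusted over the list alone (camera adjusted p = 0.127). The list was called upward under quantile normalization (adjusted p = 0.00584), median-of-ratios scaling (0.0106) and without WT replicate 2 at 15 DAP (0.0355), in a range of 0.00584 to 0.855. Of 114 auxin genes 48 went upward and 8 downward, also adjusted over the list alone (camera adjusted p = 0.178). That list was called upward under quantile normalization (adjusted p = 0.0201) and median-of-ratios scaling (0.0449), in a range of 0.0201 to 0.855. Carotenoid cleavage had 0 of 7 upward and 3 downward, also adjusted over the list alone (camera adjusted p = 0.0745). It was called downward with a pseudocount of 0.1 (adjusted p = 0.0445), among cleaned lists (0.0499), without WT replicate 2 at 15 DAP (0.0433) and without mutant replicate 1 at 25 DAP (0.049), in a range of 0.0433 to 0.513. Of 62 organic acid genes 17 went upward and 13 downward, also adjusted over the list alone (camera adjusted p = 0.143, direction downward; median 0.16, or -0.14 after median-of-ratios scaling and -0.07 after quantile normalization). They were called downward under median-of-ratios scaling (adjusted p = 0.0418; 0.0418 to 0.855 over the alternatives). Chlorophyll breakdown had 1 of 11 upward and 3 downward, also adjusted over the list alone (camera adjusted p = 0.0745). Its downward call came without mutant replicate 1 at 15 DAP (adjusted p = 0.035; 0.035 to 0.823 over the alternatives). Senescence and proteolysis had 20 of 60 upward and 14 downward (21 and 15 adjusted over the list alone; camera adjusted p = 0.376, direction downward; median 0.62). When cleaned it was called downward with 8 of 33 upward and 11 downward (adjusted p = 0.0166; 0.0166 to 0.913 over the alternatives to the full list). Organelle and ribosomal RNA had 18 of 70 upward and 15 downward (18 and 14 adjusted over the list alone; camera adjusted p = 0.178, direction downward; median 0.23, or -0.09 and -0.26 in the scalings). The cleaned list was called downward with 8 of 43 upward and 10 downward (adjusted p = 0.0499; 0.0499 to 0.855 over the alternatives to the full list).

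From 25 to 35 DAP photosynthesis was the only list called of 32, with 35 of 83 upward in the mutant relative to WT and 5 downward (37 and 5 adjusted over the list alone; camera adjusted p = 1.12e-08; adjusted p = 0.923 with an estimated correlation). Without mutant replicate 1 at 35 DAP MADS-box factors (7 of 36 upward and 2 downward, also adjusted over the list alone; camera adjusted p = 0.11) were also called upward (adjusted p = 0.0302; 0.0302 to 0.923 over the alternatives). So were senescence and proteolysis genes (15 of 60 upward and 5 downward, also adjusted over the list alone; camera adjusted p = 0.11), at an adjusted p of 0.0325 (0.0325 to 0.923 over the alternatives). From 35 to 45 DAP the only list called was senescence and proteolysis, with 19 of 60 upward and 7 downward (20 and 8 adjusted over the list alone; camera adjusted p = 0.0144; adjusted p = 0.959 with an estimated correlation). Members of that list include proteinase inhibitors, which restrain proteolysis, and the cleaned list without them gave an adjusted p of 0.392. The call of the full list ended without mutant replicate 1 at 35 DAP (adjusted p = 0.0671), and its range over the alternatives, the cleaned list among them, was 0.00121 to 0.959. Mannosidase MELO3C022162.2 (9.94, SE 0.91) and VAN3-binding protein (MELO3C006503.2, 9.38, SE 0.56) went up in the mutant relative to WT over this step.

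The 3 step differences called 8788 genes (6531 upward, 2257 downward), 6023 (2326 and 3697) and 4438 (2105 and 2333). The F test for any interaction of genotype and age called 12985 of 17658 genes, 73.5%. Median-of-ratios scaling split the first step difference into 4878 and 3686 and quantile normalization into 3654 and 4281, and the second into 3132 and 2959 or 2814 and 2837. The median gene of the first stood at 0.40, 0.14 and -0.05 in the 3 scalings and that of the second at -0.17, -0.03 and -0.03. For the third, more genes went upward than downward without replicate 1 of the WT at 35 DAP (1804 and 1745) or at 45 DAP (1915 and 1896).

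**Figure D4:**
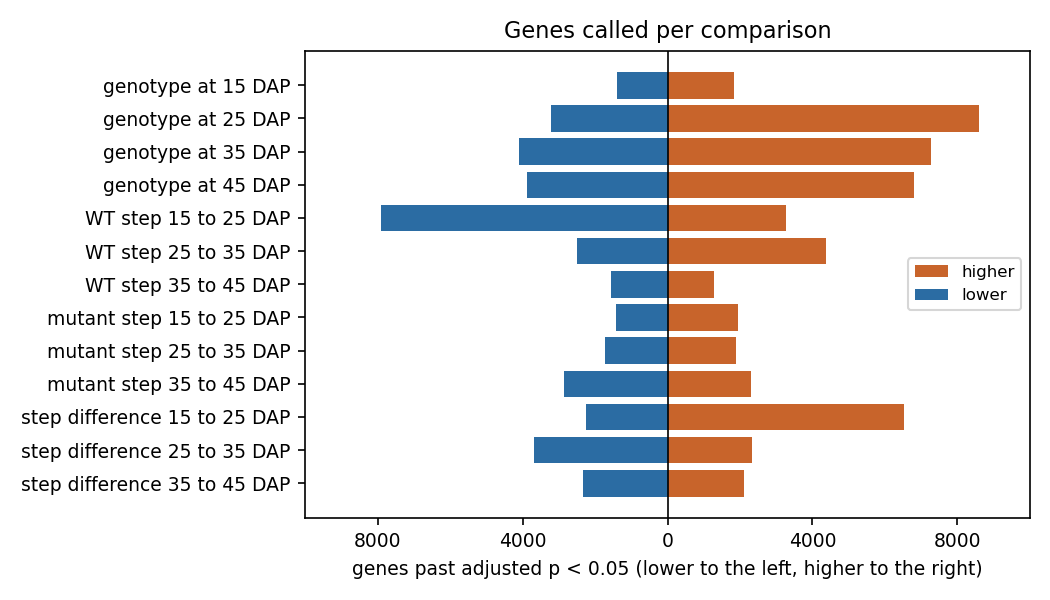
Genes called per comparison at an adjusted p under 0.05, as bars to the right of 0 for higher and to the left for lower (mutant minus WT, later minus earlier age, or mutant step minus WT step). The genotype comparison rises from 3232 calls at 15 DAP to 11815 at 25 DAP.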

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

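The tests of composition and of rind tissue were chosen only after the result was seen, and the tests of clock genes and of other splits before it.

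Changes that differed between genotypes drew attention by the test of the difference itself, which called 8788 genes from 15 to 25 DAP, 6023 from 25 to 35 DAP, 4438 from 35 to 45 DAP and 12985 for any interaction of genotype and age. From 15 to 25 DAP the largest differences of log2 change upward in the mutant were 10.58 for gibberellin-regulated protein 2 (MELO3C011008.2), 9.01 for a BTB/POZ-like gene (MELO3C016232.2) and 8.09 for a methyltransferase (MELO3C012305.2). Downward they were -8.83 and -8.23 for the chlorophyll a-b binding genes MELO3C002727.2 and MELO3C012912.2. The value for Orf108a (MELO3C029448.2), -9.12, rests on groups listed at 0 (WT at 15 DAP and mutant at 25 DAP) and is no measure of size. Over this step the lists called were photosynthesis (camera adjusted p = 1.66e-26), carotenoid synthesis (0.00794) and phloem (0.0163). With an estimated correlation none held (adjusted p = 0.179, 0.823 and 0.855).

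From 25 to 35 DAP the largest differences were 8.92 for a SWEET transporter (MELO3C026184.2), 8.53 for a CBL-interacting kinase (MELO3C035201.2) and 7.19 for a calcium-binding EF-hand gene (MELO3C010869.2) upward in the mutant. Downward they were -7.18 for a ZAT12-like zinc finger gene (MELO3C023840.2), -7.09 for a cysteine-rich transmembrane gene (MELO3C012630.2) and -7.26 for SMR4 (MELO3C023871.2), which was listed at 0 in the mutant at 25 DAP. Photosynthesis was called (camera adjusted p = 1.12e-08; adjusted p = 0.923 with an estimated correlation). From 35 to 45 DAP they were 9.94 for mannosidase MELO3C022162.2, 9.38 for VAN3-binding protein (MELO3C006503.2) and 8.97 for SMR4 (MELO3C023871.2), against -8.41 for proline-rich protein MELO3C005540.2, -8.16 for a leucine-rich repeat gene (MELO3C032314.2) and -7.16 for peroxidase MELO3C014658.2. Senescence and proteolysis was called (camera adjusted p = 0.0144; adjusted p = 0.959 with an estimated correlation), in a range of 0.00121 to 0.959 over its alternatives, and one of these, the list cleaned of proteinase inhibitors, was not called (adjusted p = 0.392).

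Other splits of the libraries into groups of the same sizes bear on these counts. For the F test 1 of 100 splits, the real one, gave as many genes, and the highest other gave 9399. These splits exchange the genotypes within each age, so they bear on any genotype difference. They cannot single out an interaction of genotype and age, and no conclusion on chance is drawn for that count. For the step differences 9, 13 and 12 of 100 splits in order of age gave as many genes as the real one, with highest others of 10117, 13136 and 9038, so chance was not excluded by this count. The other splits as large, 8 of 8, 12 of 12 and 11 of 11, all kept the genotypes of at least 1 age whole. Such a split carries the genotype difference of that age into the step difference, so its large count follows from its construction. The highest count among splits that kept no age whole was 44, 2 and 3. The share of splits as large therefore cannot decide about chance for these counts. For the genotype comparisons and the steps within a genotype the 10 splits are too few for a share under 0.05, and in each 1 split, the real one, gave as many genes. The real count and the highest other were 3232 and 1168, 11815 and 3, 11370 and 29, and 10677 and 3 for the genotypes by age, 11190 and 0, 6873 and 3, and 2821 and 96 for the WT steps, and 3366 and 135, 3622 and 33, and 5164 and 13 for the mutant steps.

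Photosynthesis genes were lower in the mutant at 25 DAP. On the per-million scale the median gene stood 0.44 higher in the mutant, so a shift of the whole scale works against a lower list. A scaling that removes this shift was bound to lower the list's median. It went from -1.82 to -2.11 with median-of-ratios scaling and -2.25 with quantile normalization. Composition is argued against as the whole cause by the direction of the shift, and the test adds nothing beyond it. Harvest at another time of day stays open. The median of 4 dawn genes of the circadian clock minus that of 7 dusk genes was -1.68, just outside the central 95% of random pairs of lists (-1.60 to 1.77). That value met the bound set beforehand for this cause. The hour of harvest is not given in the labels. Rind tissue in WT samples also stays open, with the rind and cuticle list at -0.28 relative to all genes, between the bounds set for either answer. An effect of the genotype on these genes was not separated from either and stays a hypothesis.

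At 25 DAP 72.7% of calls were higher in the mutant. The 50 most abundant genes held 23.6% to 25.5% of the values in WT libraries and 15% to 17.7% in mutant libraries, and abundant transcripts lower the values of all others on this scale. Removing the 50 genes most abundant over all libraries and rescaling, chosen after the result was seen, kept the count within 1.5 times. It did not change which direction held more genes at this age. With median-of-ratios scaling 58.3% of calls were higher and with quantile normalization 48.6%, so composition may account for part of the excess. The first value lies between the bounds set and quantile normalization equalises the distributions by construction, so composition and a true excess cannot be told apart here.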

How the results depend on the processing

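Gene-by-gene array weights, removal of the 50 most abundant genes, cleaned lists and list tests on the groups of the comparison alone were tests chosen only after the result was seen; the others were planned. No named gene or list test changed direction where it was called, but the direction with more genes changed in several counts. Under quantile normalization it did so for the genotypes at 25 (5322 higher, 5639 lower), 35 (5338, 6003) and 45 DAP (4749, 5958), the first WT step (5596, 5101), the first mutant step (1872, 2056) and the first step difference (3654, 4281). Under median-of-ratios scaling it did so for the second WT step (3230, 3589), the first and second mutant steps (1692, 2054; 1952, 1953) and the later step differences (3132, 2959; 2428, 2375). It also changed for the genotypes at 15 DAP in the groups of the comparison (293, 402), with array weights (372, 461) and with a 2-fold minimum (578, 676), for the last WT step with array weights (4248, 3251) and gene-by-gene weights (3312, 2707), for the later mutant steps (595, 718; 1077, 936) and the last step difference (1340, 1207) with a 2-fold minimum, and for the second mutant step without the 50 most abundant genes (1848, 1908). All 18 counts stayed within 1.5 times the main count with a pseudocount of 0.1, without a filter, with a filter at 5 TPM, with robust moderation and without the 50 most abundant genes. The planned count model was not run because the values are not counts, and depth, which TPM do not keep, limits every value to an unknown extent. Of 577 named gene results the call ended for 70 in fits to the groups of the comparison, 49 with array weights, 4 with a pseudocount of 0.1, 2 without a filter and 1 with each scaling, and in 55 of the fits without a library. Of 224 list results, only those called could lose a call. These were 6, 4, 5 and 5 for the genotypes by age and 3, 1 and 1 for the step differences. With an estimated correlation 24 of these calls ended and 1 held, that of the abscisic acid list at 15 DAP. Calls ended for 4 with quantile normalization, 2 with median-of-ratios scaling, 2 cleaned and 1 in the groups of the comparison. They also ended in 11 of the fits without a library. Calls were gained for 7 with median-of-ratios scaling, 6 with quantile normalization, 6 cleaned, 1 in the groups of the comparison and 1 with a pseudocount of 0.1. They were also gained in 14 fits without a library. The lists that lost their call with an estimated correlation had estimates of 0.0359 (NAC factors) to 0.25 (photosynthesis). These lay above the preset of 0.01, and a larger correlation makes a call harder in this test. For the other changes the cause was not tested, except that fewer libraries were fitted where libraries were left out.

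With the replicate number as a block all 18 counts stayed within 1.5 times (3072, 11719, 11240 and 10540 genes for the genotypes at the 4 ages), 2 named gene calls ended and no list call changed. The numbers did not pair the libraries: of 84 pairs with the same number 12 had deviations correlated above 0.1 (r -0.314 to 0.312) and 25 correlated best with their own number.

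Median-of-ratios scaling gave 2515 genes lower at 25, 35 and 45 DAP. Quantile normalization gave 2617 higher and 3240 lower at these ages, and CmNAC-NOR (MELO3C016540.2) at 25 DAP stood at -1.14 (adjusted p = 0.0894; range over the alternatives 2.84e-05 to 0.0894). Array weights, whose estimation did not reach its tolerance and gave weights of 6.59e-06 to 77.1, called 833 genes for the genotypes at 15 DAP, 11039 and 7499 for the later WT steps, 645, 9913 and 10340 for the mutant steps, 11140 and 9633 for the later step differences, and 232 higher and 202 lower at all 4 ages. Gene-by-gene weights (0.221 to 4.05) gave 5987 for the genotypes at 15 DAP, 6019 for the last WT step, 6961, 7242 and 8065 for the mutant steps, 9138 and 7715 for the later step differences, and 1529 and 745 at all 4 ages. Fits to the groups of the comparison gave 695 genes at 15 DAP, 1011 for the last WT step, 705 for the first mutant step, 176 and 142 at all 4 ages, and CmNAC-NOR at 15 DAP at -3.0 (adjusted p = 0.155; range over the alternatives 1.75e-06 to 0.155).

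An added 2-fold minimum, which can only lower a count, left 1254, 6796, 6429 and 5764 genes for the genotypes by age, 6218, 2367 and 1015 for the WT steps, 1211, 1313 and 2013 for the mutant steps, and 5604, 3340 and 2547 for the step differences. It left 266 higher and 180 lower at all 4 ages and 2176 and 724 at the 3 later ages.

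Leaving out each library gave 2089 (without mutant replicate 2 at 15 DAP) to 3556 genes for the genotypes at 15 DAP, 1533 (without WT replicate 3 at 35 DAP; 1678 without replicate 1) to 3635 for the last WT step, and 1940 (without mutant replicate 2 at 25 DAP; 2051 without mutant replicate 2 at 15 DAP) to 4019 for the first mutant step. It gave 590 (without WT replicate 1 at 15 DAP) to 1049 genes higher at all 4 ages. CmNAC-NOR at 25 DAP ranged from -1.52 to -1.31 and lost its call in 5 of 6 fits.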

Other observations

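The tests of library number and of seed tissue were chosen only after the result was seen, and the test of a late WT-like change was chosen before it. Genes named in this part were chosen after their values were seen.

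Among genes at a group mean of 10 TPM or more, mutant flesh at 45 DAP had 39 at 10 times or more the mean of every other group. Each of the other groups had 0 to 8 such genes. The most abundant were an aspartic proteinase (MELO3C007408.2, 5550 ± 1440 TPM, at most 238.81 in any other library), lipid transfer protein MELO3C018657.2 (5180 ± 1550), a BURP domain RD22 gene (MELO3C003990.2, 1360 ± 397) and a DUF679 membrane protein gene (MELO3C006590.2, 1090 ± 405). Several encode wall enzymes or their inhibitors: polygalacturonase MELO3C011986.2 (913 ± 171), pectinesterase MELO3C005532.2 (344 ± 174), pectinesterase inhibitor MELO3C006266.2 (429 ± 125), a glycoside hydrolase family 28 gene (MELO3C005839.2, 255 ± 72.8) and endoglucanase 5 (MELO3C023598.2, 110 ± 30.1). The regulators were a NAC gene (MELO3C012873.2, 333 ± 49), LOB domain genes MELO3C000192.2 (76.2 ± 53.2), MELO3C022505.2 (54.7 ± 24) and MELO3C000068.2 (22.5 ± 11.5), and MYB24-like (MELO3C017315.2, 30.4 ± 8.03).

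A single library is argued against as the source of these genes, since in 100% of them (39 of 39) the lowest mutant library at 45 DAP was above all other libraries. Seed tissue is argued against as well: the seed list moved by 0.03 relative to all genes from 35 to 45 DAP in the mutant, 0 of its 61 genes were among the 39, and the storage globulin genes MELO3C012886.2 and MELO3C024414.2 stood at 4.93 ± 3.51 and 4.04 ± 0.929 TPM. Against that, the caleosin genes MELO3C026432.2 (793 ± 272) and MELO3C023038.2 (166 ± 104), oil-body proteins known also from seeds, were among the 39. Phloem and rind tissue were not excluded. The phloem list was called higher in the mutant at 45 DAP (camera adjusted p = 0.000546; adjusted p = 0.847 with an estimated correlation). Relative to WT, 10 of its 29 genes went upward from 35 to 45 DAP and 1 downward, also adjusted over the list alone (camera adjusted p = 0.273), and none is among the 39. Of the 34 rind and cuticle genes 8 went upward and 2 downward (8 and 3 adjusted over the list alone; camera adjusted p = 0.205), and lipid transfer protein MELO3C018657.2 of that list is among the 39.

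Tested genes listed at 0 in all 12 libraries of a genotype numbered 96 in the mutant and 34 in WT. Absent from the mutant table values were alpha-farnesene synthase (MELO3C016595.2), an enzyme of terpene volatile synthesis at 29.3 ± 5.94 TPM in WT at 25 DAP, cysteine proteinase inhibitor MELO3C025554.2 (110 ± 81.9 TPM in WT at 45 DAP) and a late embryogenesis abundant D-29-like gene (MELO3C016388.2, 39.7 ± 22.3 TPM at 45 DAP). A value of 0 in such a table can also be a failed estimate.

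Several clock genes differed between genotypes at the later ages, not all in the direction of their phase. LHY-like (MELO3C022302.2), a dawn gene, was at 86.6 TPM in WT and 19.6 in the mutant at 25 DAP (log2 change -2.09, adjusted p = 3e-07) and at 124 and 13.9 TPM at 35 DAP (-3.12). GIGANTEA-like (MELO3C030034.2), a dusk gene, was at 66.4 and 213 TPM at 25 DAP (1.66) and 58.7 and 279 TPM at 35 DAP (2.24). Against that, the dusk genes EARLY FLOWERING 3 (MELO3C010769.2, 126 and 54.7 TPM, -1.18, adjusted p = 2.35e-07) and ELF4-LIKE 4 (MELO3C004647.2, -0.93, adjusted p = 0.00294) were lower in the mutant at 25 DAP. The dawn gene REVEILLE 1-like (MELO3C025091.2) did not pass the test at 25 DAP (-0.23, adjusted p = 0.258) or 35 DAP (-0.03, adjusted p = 0.914) and was higher at 45 DAP (0.78, adjusted p = 0.000661). The difference of dawn and dusk medians was 0.21 at 15 DAP, within the range of random pairs (-0.66 to 0.71), and -3.68 at 35 DAP and -2.10 at 45 DAP, outside it (-1.73 to 1.92 and -1.38 to 1.84). It was largest at 35 DAP, while the photosynthesis list was lowest at 25 DAP.

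A hypothesis was that the mutant goes through part of the WT change from 15 to 25 DAP late, from 35 to 45 DAP. Across 17658 genes, which are not independent replicates, both changes correlated at r = 0.206, just above the 0.2 set for it, and 74.5% of the 3698 genes called in both moved the same way (786 rose and 1970 fell in both, against 428 and 1281 for independent lists). The mutant change from 15 to 25 DAP gave a higher r of 0.221 with 71.8% moving the same way, and that from 25 to 35 DAP r = 0.141, so the late step is not singled out.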
